A study of Gallus gallus with 20 samples.

How the data were processed

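Messenger RNA was measured by RNA sequencing in liver and breast muscle (pectoralis major) of KRC chickens, a mixed-sex flock raised from 1-day-old chicks. Per the labels, 125 chicks entered each of 2 raising systems, each housed in 5 pens. The conventional birds received commercial feed. The organic birds received feed of organic ingredients and, from day 21, access to an outdoor pasture, and slaughter age was 91 days. Feed and pasture therefore changed together and cannot be separated in these data, and the pen of each sampled bird was not used here. Each tissue has 5 conventional and 5 organic libraries, 20 in all. Groups and replicate numbers were taken from the sample titles.

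Per the labels' protocols, total RNA was extracted with TRIzol, and Illumina libraries were made. Strandedness and read layout are not given in the sources used here. The submitters' processing notes name HISAT2 2.0.5, DESeq2 1.20.0 and the genome build GRCg6a, without saying what each was used for, and the tool that counted reads per gene is not given in the sources used here. The deposited table holds whole-number read counts and FPKM values for each of 27170 genes in each library, with gene names and positions. The counts were used as the authors deposited them. The FPKM deposited by the authors equalled the count divided by gene length and by a library factor. In each of the 20 libraries that factor was the median-of-ratios size factor multiplied by the geometric mean of the library totals, so these values were already scaled between libraries. The ratio of that factor to the library's own total ranged from 0.824 to 1.19. FPKM entered alternatives only.

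The table gives no symbol for 13482 genes, and 9 symbols had been turned into dates by a spreadsheet. Of the unnamed genes, 1274 carry an NCBI gene number, and 720 of them received a symbol through a RefSeq table of the assembly GRCg7b, which was used for names only and only for matching gene lists. Because the counting rule is not given, values of genes with near-identical copies (myosins, haemoglobins, the major histocompatibility complex, IFITM genes) are uncertain. So are values of genes whose positions overlap another measured gene. Among the named ones these were MOGAT1, ACLY, EIF2AK2, RSAD2, DNAJA1, NDUFB1, ACAT2, OGN and ATP8 in liver. In breast muscle they were HSPA8, MCM5, HK2, DTX3L, TRIM63, HBBA, HMGCS1 and BF1. COL5A2 and COL3A1 overlap each other. Genes without a symbol held 9.7% to 14.6% of the counts of a library. 1 item of the table is not reported here.

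Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM scaling and the filterByExpr filter (minimum count 10), separately in each tissue. A test of whether the change differed between tissues was fitted over all 20 libraries with 4 group means. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and all tests were two-sided. The ± after a log2 fold change is its SE from that fit, and the ± after a mean CPM (TMM scaled) is the SD over 5 libraries. Log2 fold changes are organic over conventional.

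A set of 43 gene lists was written, and 37 were tested in liver and 33 in breast muscle because at least 5 members passed the filter. Each list was compared with all other tested genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 CPM of its members in a library. Members were also tested adjusted over the list alone, which does not correct for the number of lists tested.

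Genes were named by a fixed rule. Per tissue it took the 12 largest changes in each direction among genes past the threshold or, as happened here, the 5 genes with the smallest p, given as values that did not pass. It was read as the 5 such genes that have a symbol. From each list it took the members past the threshold, or otherwise up to 4 members with the smallest p, and for the test between tissues the 5 genes with a symbol and the smallest p. Any other named gene is said to have been chosen after its values were seen.

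Total counts ranged from 14065269 to 20488526 per liver library and from 12699692 to 13417005 per breast muscle library. The methods were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes in each of 5 simulations. In the liver comparison over 13186 genes, edgeR recovered 84.2% of genes changed 4-fold, 47.8% of those changed 2-fold and 6.27% of those changed 1.5-fold, and 4.38% of its calls were false. In the breast muscle comparison over 12496 genes, the shares were 90.9%, 53.4% and 10.7%, and 6.87% of calls were false. In the test between tissues over 14447 genes, they were 62.4%, 17.6% and 2.09%, and 3.2% of calls were false. DESeq2 1.42.0 on the same simulated counts recovered 67.8% of the 2-fold genes in liver and 67.2% in breast muscle, with 17.9% and 18.1% of its calls false. With the interferon-stimulated list raised 1.5-fold, camera with either correlation called that list in 5 of 5 simulations of each tissue. The simulated genes varied independently of each other, unlike genes in tissue.

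The tests, the gene lists, the rule for naming genes and the alternatives that follow were fixed before the data were examined. The alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter of 1 CPM in 5 libraries, DESeq2, limma-voom with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), non-robust dispersions, W-linked expression as a covariate, the replicate number as a block, 1 fit of all 20 libraries, an added limit of 1 on the absolute log2 fold change, and leaving out each library in turn. After the data were seen, the counts of liver organic replicate 1 were also thinned at random, in 100 draws, to the median total of the other liver libraries. No 2 libraries of a group were the same library: over 40 pairs the chi-square of their counts per degree of freedom was at least 27. An exact permutation test of list scores was added later. Of the 126 possible splits of the libraries into groups of 5, 100 were used, the real one and others drawn at random, and 40 of these, the real one among them, with DESeq2. Counts of splits with a result as large include the real one.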

Results

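RNA sequencing profiled liver and breast muscle of chickens from a conventional and an organic raising system, in 4 groups of 5 libraries. Whether the liver and muscle libraries come from the same birds is not given in the labels. Liver libraries held 14065269 to 15175691 counts, except for organic replicate 1 with 20488526, and breast muscle libraries held 12699692 to 13417005. Mitochondrial transcripts took 5.79% to 14.2% of the counts in liver and 3.27% to 5.6% in breast muscle.

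Each library showed the transcripts of its labelled tissue. The median of the hepatocyte markers was 11.96 to 13.02 log2 CPM in the liver libraries and -2.83 to -1.13 in the breast muscle libraries. The median of the skeletal muscle fibre markers was 12.74 to 13.49 in breast muscle and -2.83 to -1.42 in liver. Genes of chromosome W, which hens carry and cocks do not, had 31 to 264 counts in all per library. None of the 14 named W genes, among them SPIN1W and NIPBLL, exceeded 1 count in any library, although the labels describe chicks of both sexes. The median of genes on chromosome Z, relative to the autosomes and to the mean of the tissue, lay between -0.06 and 0.05 on the log2 scale in all 20 libraries.

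The liver comparison asked which genes differ by raising system. Livers of organic birds held more transcript of interferon-stimulated genes, the antiviral genes that cells switch on in response to interferon. Of 26 measured members of this list, 24 were higher, and 11 passed the threshold adjusted over the list alone, all of them higher. OASL, an antiviral protein of the oligoadenylate synthetase family, stood at 43.6 ± 19.6 CPM (SD, n = 5) in conventional and 144 ± 55.7 CPM (SD, n = 5) in organic livers, a log2 fold change of 1.73 ± 0.36. IFIT5, which binds viral RNA, was at 1.44 ± 0.37, ZNFX1, an RNA sensor, at 1.01 ± 0.25, and EIF2AK2, the kinase PKR, at 0.81 ± 0.21. Each was above the conventional mean in 5 of 5 organic libraries and above every conventional library in 4 of 5. The other members past it, 7 in number and named after their values were seen, were IFI6 at 1.77 ± 0.48, MX1 at 1.57 ± 0.51, CMPK2 at 1.47 ± 0.39, RSAD2 at 1.12 ± 0.40, IFITM3 at 0.88 ± 0.26, DHX58 at 0.51 ± 0.18 and PARP12 at 0.49 ± 0.14. Across all genes tested, 0 members passed with edgeR, where 12 had an unadjusted p under 0.05, and 5 passed with DESeq2 (OASL, IFI6, IFIT5, CMPK2 and ZNFX1). The list ranked above other genes with the preset correlation (adjusted p = 1.46e-11), and the call was lost with an estimated correlation (adjusted p = 0.802). The groups overlapped in the list score: conventional replicate 3 stood at 5.55, above organic replicates 2 (5.39) and 5 (5.35).

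**Figure D1:**
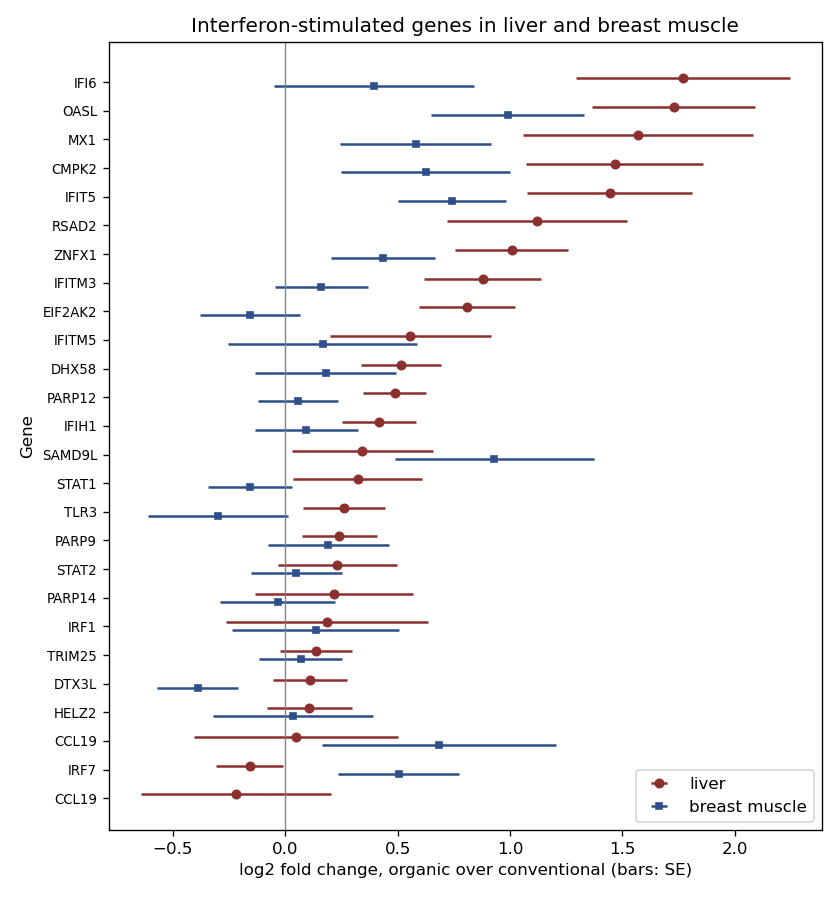
Log2 fold change (x axis, organic over conventional birds) of each member of the interferon-stimulated list, in liver (circles) and breast muscle (squares), with 5 libraries per group and bars of 1 SE; CCL19 appears at 2 gene identifiers. In liver 24 of 26 members lie above 0, with IFI6 at 1.77 and OASL at 1.73, and in breast muscle 19 of 24 do.

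Genes of lipid synthesis stood higher in organic livers by list, though not in each of them. ACLY, which makes the acetyl-CoA used for fatty acids and cholesterol, was at 388 ± 65.5 CPM (SD, n = 5) in conventional and 752 ± 173 CPM (SD, n = 5) in organic livers, a log2 fold change of 0.95 ± 0.18, above every conventional library in 5 of 5 organic libraries. It was the 1 of 22 measured members of the fatty acid synthesis and desaturation list to pass adjusted over the list alone (adjusted p = 0.00469). FASN, the fatty acid synthase, was at 2.15 ± 0.64, LPIN1 at 0.70 ± 0.24 and ELOVL2, an elongase of polyunsaturated fatty acids, at -1.22 ± 0.40. Of the list, 18 members were higher and 4 lower. In the cholesterol synthesis list 20 of 21 members were higher, with a median log2 fold change of 0.82, and 0 passed adjusted over the list alone. ACAT2 was at 1.11 ± 0.39 and CYP51A1, the lanosterol demethylase, at 1.10 ± 0.42, which were 0.73 without organic replicate 3 and 0.63 without organic replicate 1, respectively. The score of this list had an SD of 0.80 among organic livers (n = 5) and of 0.22 among conventional livers (n = 5). For both lists organic replicates 3 and 5 scored below the conventional mean. The cholesterol score difference of 0.47 was 0.23 without organic replicate 1 and 0.31 without organic replicate 4, and the fatty acid score difference of 0.38 was 0.16 without organic replicate 1 and 0.58 without organic replicate 3. Both lists ranked above other genes with the preset correlation (adjusted p = 0.00592 and 6.22e-05), and neither did with an estimated correlation (adjusted p = 0.802 for both).

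Heat shock and unfolded protein response genes, which encode chaperones, were higher for 27 of 29 members in organic livers. HSPA5, the chaperone BiP of the endoplasmic reticulum, was at 1.32 ± 0.44, SDF2L1 at 1.01 ± 0.31 and DNAJA1 at 0.89 ± 0.30. Organic replicate 1, the deepest liver library, had the highest score of this list, and the score difference between groups was 0.52 with it and 0.32 without it. Without it HSPA5 was at 0.85 and DNAJA1 at 0.56. Ribosomal protein genes were higher for 55 of 55 members, with a median log2 fold change of 0.25 and RPL29 at 0.46 ± 0.17. Their score in organic replicate 5 was -0.05 relative to the conventional mean. The score difference of 0.23 was 0.17 without organic replicate 1 and 0.18 without conventional replicate 1. Nuclear genes of oxidative phosphorylation were higher for 42 of 44 members, with NDUFB1 at 0.51 ± 0.14. Their score difference of 0.19 was 0.13 without organic replicate 1 and 0.13 without organic replicate 2. Organic replicates 4 and 5 scored -0.019 and -0.024 relative to the conventional mean. The mitochondrially encoded genes were higher for 13 of 13, with ATP8 at 0.37 ± 0.24. The difference of the mitochondrially encoded score rested mostly on organic replicate 4, which had 14.2% mitochondrial counts against 5.79% to 9.25% in the other livers. The score difference of 0.20 was 0.065 without that library, where ATP8 was at 0.24, 0.12 without conventional replicate 5 and 0.33 without organic replicate 1. Antioxidant and NRF2 target genes were higher for 20 of 25 members, led by FTH1, the ferritin heavy chain, at 0.43 ± 0.15 and TXNRD1, thioredoxin reductase, at 0.66 ± 0.23. None of these members passed adjusted over its list alone. All 5 lists ranked above other genes with the preset correlation, with adjusted p from 1.36e-17 to 0.0108, and none did with an estimated correlation, with adjusted p from 0.802 to 0.911.

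Matrix genes stood lower in organic livers. Of the collagens and matrix list 21 of 23 members were lower, with COL5A2 at -0.48 ± 0.13, COL3A1 at -0.53 ± 0.17 (their positions overlap), COL6A1 at -0.56 ± 0.19 and FN1, fibronectin, at -0.39 ± 0.14. Of the fibroblast and stellate cell markers, which share collagens with that list, 13 of 15 were lower, with OGN at -0.81 ± 0.31 and LUM at -0.72 ± 0.34. Both lists ranked below other genes with the preset correlation (adjusted p = 8.12e-06 and 0.00518) and not with an estimated correlation (adjusted p = 0.802 for both). Markers of white blood cells gave no call: the T cell list had 14 of 17 members lower (adjusted p = 0.633), with CD3E at -0.41 ± 0.23 (-0.27 without conventional replicate 3 and -0.25 without conventional replicate 5), the macrophage list 7 of 14 lower (adjusted p = 0.907), with MARCO at -0.10 ± 0.24 (from -0.29 to 0.11 with 1 library left out), the heterophil list 6 of 7 lower (adjusted p = 0.356), and the B cell list 5 of 7 higher (adjusted p = 0.406).

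The other liver lists did not pass with the preset correlation. Among their members with the smallest p, NPAS2, a clock transcription factor, was at -1.67 ± 0.46 and BHLHE41, a clock repressor, at 1.48 ± 0.58. CYP1B1, a xenobiotic oxidase, was at -1.22 ± 0.34, ABCB11, the bile salt export pump, at -0.74 ± 0.24, and CPS1, which makes carbamoyl phosphate, at -1.09 ± 0.41. PLIN2, a coat protein of lipid droplets, was at 1.23 ± 0.38, and UGP2, which makes the glucose donor for glycogen, at 1.09 ± 0.33, which was 0.62 without organic replicate 1. The xenobiotic metabolism list (15 of 27 members higher, adjusted p = 0.953) and the hepatocyte markers (10 of 13 higher, adjusted p = 0.808) showed no common direction by that test. The sign of the test, the median and the mean of the log2 fold changes differed for the immediate early, adipocyte, thrombocyte, antigen presentation, macrophage and glucose and glycogen lists.

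Over all 13186 genes tested in liver, 0 passed with edgeR, and the smallest adjusted p was 0.493. At an unadjusted p under 0.05 there were 997 genes, 473 higher and 524 lower, where 659.3 are expected by chance. The groups did not overlap for 1.21% of genes, where chance gives 0.79%. The 5 genes with a symbol and the smallest p did not pass. They were MOGAT1 (ENSGALG00000005217, GRCg6a chromosome 9, 8181677 to 8204484), an acyltransferase of triglyceride synthesis, at -1.24 ± 0.22; SLC37A1 (ENSGALG00000016185, chromosome 1, 110776509 to 110811358), a sugar phosphate transporter, at -1.04 ± 0.19; PXK (ENSGALG00000007052, chromosome 12, 12191823 to 12223412) at 0.85 ± 0.16; ACLY (ENSGALG00000003475, chromosome 27, 7521200 to 7545007), described above; and ANKRD28 at -0.84 ± 0.16. For each of the 5, all 5 organic libraries lay beyond all 5 conventional libraries. The 5 genes were picked by their p, so this adds no evidence. DESeq2 called 31 liver genes, 20 higher and 11 lower. They included ACLY, FTH1, MOGAT1, OASL, SLC37A1, PXK, ANKRD28, IFIT5 and ZNFX1 and, chosen after their values were seen, IFI6, CMPK2, the taurine transporter SLC6A6 (-1.34 ± 0.28 in the edgeR fit), the interleukin-33 receptor IL1RL1 (0.90 ± 0.19) and HAO2 (-1.03 ± 0.22).

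The breast muscle comparison asked the same question in pectoralis major. Among clock genes, BHLHE40 and BHLHE41, repressors of the circadian clock, were higher in organic birds, and RORA, an activator in the clock, was lower. These 3 of 16 measured clock genes passed adjusted over the list alone (adjusted p = 0.00957, 0.00957 and 0.0332), each on its side of the conventional mean in 5 of 5 organic libraries. BHLHE40 stood at 358 ± 82.3 CPM (SD, n = 5) in conventional and 699 ± 230 CPM (SD, n = 5) in organic muscle, a log2 fold change of 0.97 ± 0.23. BHLHE41 was at 0.76 ± 0.19, RORA at -0.94 ± 0.29 and CLOCK at -0.48 ± 0.18. ALDH1A2, which makes retinoic acid, was lower at -1.03 ± 0.24, below every conventional library in 5 of 5 organic libraries, and was the 1 of 13 vitamin A genes to pass adjusted over the list alone (adjusted p = 0.011). Among clock genes named after their values were seen, PER2 was at 0.73 ± 0.32 and NR1D1 at 0.63 ± 0.24. Across all genes tested, none of these passed with edgeR, and BHLHE40 passed with DESeq2 (adjusted p = 0.0477). The hour of collection was not used here, and a difference in it between the groups cannot be told apart from the raising system.

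The genes of muscle growth and wasting with the smallest p stood in both directions, and none passed. FBXO32, the ubiquitin ligase atrogin-1 of muscle wasting, stood at 467 ± 240 CPM (SD, n = 5) in conventional and 928 ± 270 CPM (SD, n = 5) in organic muscle, a log2 fold change of 0.99 ± 0.33, and FOXO3, a transcription factor that drives it, was at 0.92 ± 0.27. MYMK, the fusion protein myomaker, was at -1.23 ± 0.37, and PAX7, a marker of muscle stem cells, at -0.91 ± 0.32. Each kept its side of the conventional mean in 5 of 5 organic libraries, and 0 of 21 members passed adjusted over the list alone. Chosen after their values were seen, FOXO1 was at 0.75 ± 0.29, the ubiquitin ligase TRIM63 at 0.83 ± 0.39 and MYOD1 at -0.73 ± 0.27. The list had no common direction with camera (adjusted p = 0.765), and it passed fry's test for change in either direction (adjusted p = 0.0334), the 1 list of 33 to do so. That result was not set against other splits of the libraries.

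Cell cycle genes were lower for 21 of 24 members in organic muscle, with a median log2 fold change of -0.59; MCM3, a subunit of the replicative helicase, was at -1.11 ± 0.36 and MCM5 at -0.74 ± 0.25. Heat shock and unfolded protein response genes were higher for 24 of 30 members, with the chaperones HSPA8 at 1.52 ± 0.46 and HSP90AA1 at 1.41 ± 0.42 and HSP90B1 at 0.48 ± 0.14. Muscle glycolysis genes were higher for 20 of 23 members, with HK2, a hexokinase, at 0.71 ± 0.20 and GPI at 0.37 ± 0.14. The members with the next smallest p went the other way, PFKFB4 at -0.45 ± 0.20 and PPP1R3A at -0.31 ± 0.18 (-0.16 without conventional replicate 3). Interferon-stimulated genes were higher for 19 of 24 members, with IFIT5 at 0.74 ± 0.24 and OASL at 0.99 ± 0.34. Next by p were DTX3L at -0.39 ± 0.18 (-0.26 without conventional replicate 3) and SAMD9L at 0.93 ± 0.44 (0.58 without organic replicate 4). Clock genes were higher for 11 of 16 members. Endothelial markers were lower for 13 of 16 members, with PLVAP at -0.51 ± 0.22 and TIE1 at -0.43 ± 0.19. These 6 lists passed with the preset correlation, with adjusted p from 4.66e-06 to 0.0498, and none with an estimated correlation (adjusted p = 0.626 for each). Apart from the 3 clock genes, none of their members passed adjusted over the list alone. The glycolysis, interferon and endothelial calls were lost without organic replicate 5, leaving 3 lists, while their score differences stayed near their full values (0.155, 0.246 and -0.183 without it, 0.154, 0.229 and -0.191 with it). The interferon score difference of 0.23 was 0.14 without organic replicate 3, where OASL was at 0.62. The cell cycle score difference of -0.50 was -0.32 without conventional replicate 1 and -0.34 without organic replicate 1. Relative to the conventional mean, conventional replicate 1 scored 0.70 and organic replicates 1 and 2 scored -1.15 and 0.08 for this list. The named cell cycle genes were weakly expressed. Mean CPM in conventional and organic muscle was 2.75 and 1.26 for MCM3 and 4.98 and 2.98 for MCM5. The endothelial score difference of -0.19 was -0.11 without conventional replicate 1, where TIE1 was at -0.26, and -0.29 without conventional replicate 3.

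**Figure D2:**
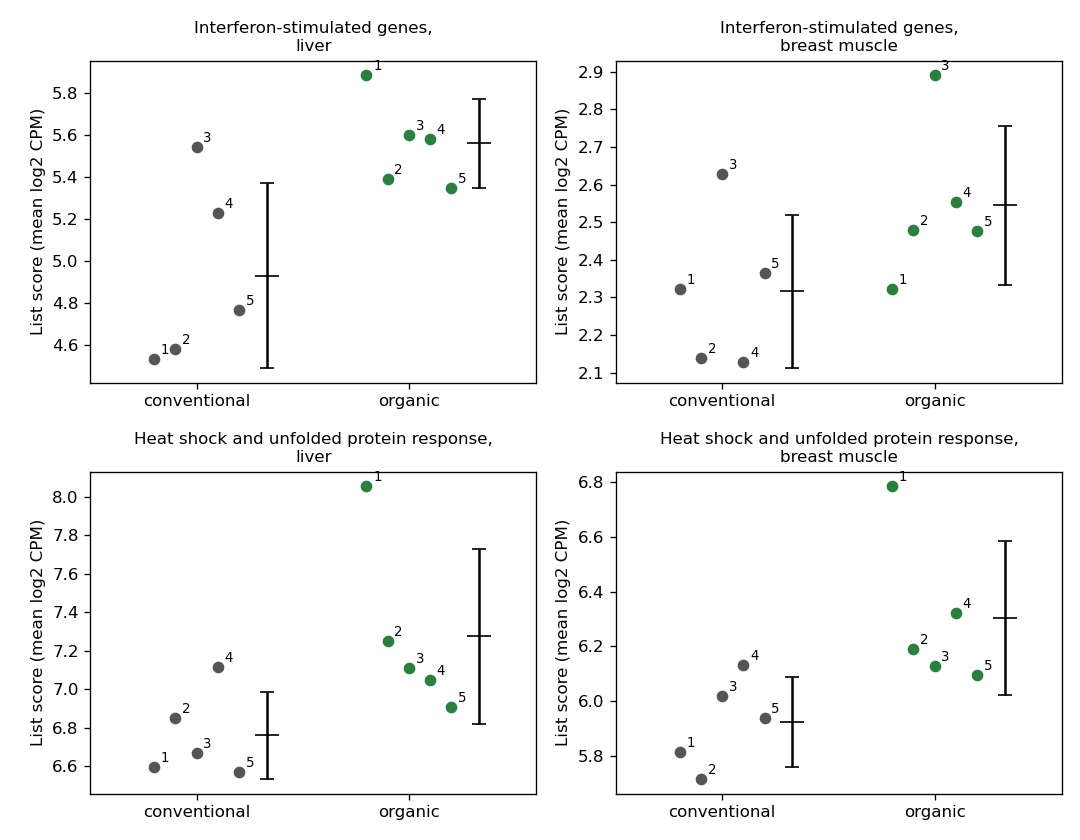
List score (y axis, mean log2 CPM of the members) of the interferon-stimulated and the heat shock lists in each library of liver and breast muscle; points are libraries with their replicate numbers, and the bars at the right of each group show its mean ± SD (n = 5). Organic replicate 1 has the highest heat shock score in both tissues, 1.30 above the conventional mean in liver and 0.86 in breast muscle.

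Other lists did not pass in breast muscle. Slow-twitch fibre genes had a median log2 fold change of -2.47 (8 of 9 members lower, adjusted p = 0.4) that rested on conventional replicate 1, which was the highest of 10 libraries for 8 of the 9 genes. MB, myoglobin, stood at 77.9 CPM in that library and at 0.429 to 6.78 CPM in the other 9, and MYH7B, a slow myosin chosen after its values were seen, at 430 CPM against 0.177 to 30.4 CPM. Without that library the log2 fold change of MB was 0.024. Fast-twitch fibre genes were higher for 13 of 20 members (adjusted p = 0.684), with the myosin MYH1C at -0.93 ± 0.38. The haemoglobins HBA1 and HBBA were at 1.42 ± 0.60 and 1.46 ± 0.62 (erythrocyte markers, adjusted p = 0.508), and at 0.48 and 0.51 without organic replicate 4, the library with the highest erythrocyte score. The erythrocyte score difference of 0.36 was 0.051 without it and 0.55 without organic replicate 1. HMGCS1 of cholesterol synthesis was at -0.33 ± 0.12 (15 of 20 members lower, adjusted p = 0.133), LPIN1 at -0.92 ± 0.35 and ELOVL6 at -0.97 ± 0.39 (fatty acid synthesis, 12 of 18 lower, adjusted p = 0.371). BF1, of the major histocompatibility complex, was at -0.82 ± 0.31, the glucocorticoid target KLF9 at 0.64 ± 0.25 and the stress gene GADD45B at 1.03 ± 0.41. The sign of the test, the median and the mean differed for the fast-twitch, collagen, nuclear oxidative phosphorylation, adipocyte and amino acid response lists.

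Over all 12496 genes tested in breast muscle, 0 passed with edgeR, and the smallest adjusted p was 0.567. At an unadjusted p under 0.05 there were 934 genes, 420 higher and 514 lower, where 624.8 are expected by chance. The groups did not overlap for 1.23% of genes, where chance gives 0.79%. The 5 genes with a symbol and the smallest p did not pass. They were TRAIL-LIKE (ENSGALG00000007240, chromosome 4, 9589706 to 9595509), named for its likeness to a death ligand of the tumour necrosis factor family, at -1.15 ± 0.24, ARHGEF10L (ENSGALG00000043128, chromosome 21, 135941 to 156749), at -0.97 ± 0.21, the transcription factor SOX13 at -1.37 ± 0.30, the cadherin FAT1 at -1.18 ± 0.26, and GALNT17, a glycosyltransferase, at -0.97 ± 0.22. Without conventional replicate 4, edgeR called 1 gene, ARHGEF10L, at -1.15. DESeq2 called 15 genes, 9 higher and 6 lower, among them these 5 and BHLHE40 and, chosen after their values were seen, the kinase PIM1 (1.96 ± 0.54 in the edgeR fit, and 1.06 without organic replicate 3) and the fructose transporter SLC2A5 (1.58 ± 0.39).

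Whether the raising system acted differently in the tissues was tested over all 20 libraries. Of 14447 genes, 0 passed with edgeR (smallest adjusted p = 0.816) and 0 with DESeq2, and 771 had an unadjusted p under 0.05, where 722.4 are expected by chance. The 5 genes with a symbol and the smallest p, none of which passed, all had a lower change in liver than in breast muscle. They were CMC4 with a difference of -0.67 ± 0.15, SLC6A6 with -1.67 ± 0.40, ZSWIM5 with -1.07 ± 0.26, SKI, a repressor of transforming growth factor signalling, with -1.38 ± 0.33, and MOGAT1 with -1.86 ± 0.46. SLC6A6 stood at 88.5 ± 30.1 CPM (SD, n = 5) in conventional and 35.2 ± 9.45 CPM in organic livers, scaled over all 20 libraries, and at 6.33 ± 1.80 and 8.04 ± 2.78 CPM in breast muscle.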

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

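The tests chosen only after the result was seen were those of the edgeR counts, of the muscle clock genes and of the members past the threshold summed over lists against other splits, of single organic libraries and of white blood cells for the interferon genes, and the tests of the heat shock genes other than that over all lists. The other tests over splits were chosen before their own outcome was seen, but after the main comparisons.

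Other splits of the same libraries show how far chance reaches; each count of splits includes the real one. With edgeR the real grouping gave 0 genes in liver, in breast muscle and between tissues, where DESeq2 called 31, 15 and 0 and 997, 934 and 771 genes had an unadjusted p under 0.05. A count of 0 is reached by any split, 100 of 100 in each case, so it tests nothing; the highest other splits gave 2, 65 and 9 genes. The split with 65 muscle genes differs from the real one by the exchange of 1 organic and 1 conventional library, and what sets it apart was not identified. As many genes at an unadjusted p under 0.05 came from 12, 12 and 17 of 100 splits, the highest other splits giving 1981, 1653 and 1207. For the 31 liver genes called by DESeq2, 5 of 40 splits gave as many, the highest other split 181. For the 15 muscle genes called by DESeq2, 12 of 40 splits gave as many, the highest other split 220 genes. Camera with the preset correlation called 10 lists in liver and 6 in breast muscle, and 64 and 75 of 100 splits gave as many, up to 19 and 14 lists. In breast muscle the most members past the threshold adjusted over the list alone were the 3 clock genes, and 40 of 100 splits had some list with as many, up to 37. Summed over lists, 12 members in liver and 4 in breast muscle passed adjusted over the list alone, ACLY and ALDH1A2 among them. As many came from 23 and 59 of 100 splits, the highest other splits giving 50 and 69. Chance cannot be excluded for the unadjusted, DESeq2 and list counts or for these sums.

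Interferon-stimulated genes in organic livers had 11 members past the threshold adjusted over the list alone. Of 100 splits, 1, the real one, gave as many. The highest other split gave 10 and differs from the real one by the exchange of 1 organic and 1 conventional library. The median other split gave 0. However, this list was looked at because it stood out among 37. When any list was allowed to stand out, 11 of 100 splits had a list with as many members, up to 23 members, so chance cannot be excluded for the pattern as it was found. A single library as the cause is argued against, since at least 87.2% of the list score difference of 0.63 ± 0.22 (SE) remained without any 1 organic library and at least 84.2% without any 1 conventional library. The macrophage and T cell score differences were 0.005 and -0.103, with 0.378 and 0.491 at 2 SE above them. These limits lie below 0.63 but above 0.193, the interferon difference less 2 SE, so more macrophages or T cells cannot be excluded. More B cells stay open (0.29, with 0.78 at 2 SE above it), as do, untested, pens and the raising system itself, with its feed and outdoor contact with microbes.

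Heat shock genes were higher in organic birds in both tissues, by a list score of 0.52 ± 0.23 (SE) in liver and 0.38 ± 0.15 in breast muscle. Of the 126 joint splits of the replicate numbers, 3 gave differences as large in both tissues, the real one included, and the highest other split reached 0.394 for the smaller of its 2 differences, against 0.379. This list was also picked from 28 tested in both tissues, and 15 of 126 splits had some list that moved as far in both, with 3.38 as the highest other value of the smaller t and 2.27 in the real split, so chance cannot be excluded. Organic replicate 1 as the whole cause is argued against, since at least 61.9% of the difference remained without organic replicate 1. Its liver library scored 1.30 above the conventional mean and 1.29 once thinned to 14813730 counts (mean of 100 draws), against 0.49 for the highest other organic liver. Random thinning keeps the share of each gene, so this shows only that the number of counts itself did not raise the score. What set that library apart stays open, as the labels do not tie it to muscle organic replicate 1 (0.86 above the conventional mean). Different times or handling at collection would go with the groups, and so cannot be told apart from the raising system. The immediate early genes do not settle this and were variable, their score difference in muscle reaching 0.536 at 2 SE above its value.

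A check for libraries far from the others of their group of 5 covered 390 sets of values and picked out 16, where chance alone picks out about 19.5. Among library measures it picked out the total of liver organic replicate 1, at 20488526 counts against 14360757 to 15071735 in the others. Among list scores it picked out slow-twitch fibre genes in muscle conventional replicate 1 (7.32 against 2.70 to 3.94), heterophil markers in liver organic replicate 5 (2.92 against 2.35 to 2.47), ribosomal proteins in liver conventional replicate 1 (7.96 against 8.19 to 8.24) and apolipoproteins in liver conventional replicate 2 (6.83 against 6.76). In log2 CPM, liver organic replicate 1 was highest for UGP2 (10.96) and HSPA5 (11.79), and liver conventional replicate 2 was lowest for UGP2 (8.13). Liver conventional replicate 4 was lowest for COL3A1 (7.09), HAO2 (4.89) and SLC6A6 (5.32) and highest for CYP51A1 (7.62). Liver conventional replicate 1 was lowest for RPL32 (7.65), and liver conventional replicate 5 for NDUFS6 (4.83). In breast muscle, conventional replicate 3 was lowest for HBA1 (4.31) and organic replicate 4 for TRIM63 (9.04).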

How the results depend on the processing

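The exact permutation test of list scores, all settings of the count of interferon-stimulated members, the list score differences without 1 library and the test of whether equal numbers mark 1 bird were chosen only after the result was seen. The count of genes past the threshold with edgeR stayed at 0 in both tissues and between tissues under every alternative except 2. DESeq2 called 31 genes in liver and 15 in breast muscle, and 0 between tissues. Leaving out 1 library gave 0 to 1 genes in breast muscle, the 1 without conventional replicate 4. In the simulations DESeq2 made more false calls than edgeR, and the cause in the real data was not tested.

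The 10 liver lists became 0 with an estimated correlation, 0 with fry and 0 with the exact permutation test, and the 6 muscle lists became 0, 0 and 0. The preset correlation assumes that genes of a list vary almost independently, and the estimate does not. The exact permutation test has a smallest p of 0.00794, which 1 list alone could not carry past adjustment over 37 or 33 lists, and in the simulations it missed the changed list every time. W-linked expression as a covariate left 3 muscle lists, and leaving out 1 library left 3 to 9, and the cause was not tested. No named W gene exceeded 1 count in any library, so this covariate cannot tell whether sex played a part. The chromosome Z medians, relative to the autosomes, were -0.047 to 0.048 in liver and -0.059 to 0.049 in muscle. These narrow ranges show no division of the libraries by sex. They argue against a mix of sexes among the libraries, and so against sex as the source of a group difference. The interferon-stimulated count of 11 stayed between 8 and 12 throughout. The heat shock score differences of 0.52 and 0.38 were 0.32 and 0.26 without organic replicate 1.

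Equal replicate numbers did not pair organic with conventional libraries, whose deviations correlated at -0.18 to 0.16 in liver and -0.18 to 0.08 in muscle. Between tissues the correlation over 11351 genes was 0.03 to 0.24, with 9 of 10 liver libraries closest to their own number among the 5 of their group, and over the 300 most variable genes it was 0.22 to 0.43, with 10 of 10. This is a hint from the data, not the design, that equal numbers in liver and muscle may mark the same bird. The replicate number as a block gave 0 genes in each comparison, 10 lists in liver and 5 in breast muscle, and between tissues the block was raising system with number.

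None of the 122 values of named genes passed in the main fit, so keeping the side of the threshold means only staying uncalled, however far a value moved. Over these values and 2728 alternatives, 2703 kept direction and side of the threshold, and 23 passed it, 22 of these with DESeq2. The sign turned in 2, neither of them a call: MARCO in liver ranged from -0.29 to 0.11 when 1 library was left out, and MB in breast muscle from -3.07 to 0.024, reaching 0.024 without conventional replicate 1. Depth limits genes near the filter, and at n = 5 changes of 1.5-fold were mostly missed in simulation.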

Other observations

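Neither test in this part was chosen after its own outcome was seen, but the gene SLC37A1 and the correlation of fold changes were picked after the main comparisons.

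SLC37A1 stood lower in organic birds in both tissues, at -1.04 ± 0.19 in liver and, chosen after its value was seen, at -0.82 ± 0.19 in breast muscle, where it stood at 12.6 ± 3.18 CPM (SD, n = 5) in conventional and 7.11 ± 0.623 CPM (SD, n = 5) in organic birds. It did not pass over all genes with edgeR in either tissue. A hypothesis is that birds differ in this gene in a way both tissues share, as a variant near the gene would give. Within the groups, log2 CPM of liver and muscle of equal number, taken as 1 bird although the labels do not say so, correlated over 10 numbers (Pearson r = 0.866, permutation p = 0.00558; Spearman rho = 0.733, permutation p = 0.0265, with 100000 resamples). This was the 1 gene so tested, chosen because it stood low in both tissues. Without the 2 numbers farthest from the median in liver r was 0.567, so the relation leans on them. These values are consistent with a difference shared by the tissues of a bird, and a genotype was not analysed here.

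Fold changes of the tissues went together weakly across 11351 genes (r = 0.254; genes are not independent replicates). Of 100 joint splits of the numbers, the real one included, 8 gave a correlation as high, the highest other 0.33 and the median other 0.171, so chance cannot be excluded.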
